A study of Mus musculus with 4 samples.

How the data were processed

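Single-cell RNA was measured in 4 libraries of Cd45+ cells sorted from MC38 tumours, which are grown from a mouse colon cancer cell line, about 19 days after the tumour cells were injected into the flanks of mice. Per the labels, 2 libraries came from p53+/-, Lck-Cre mice (WT 1 and WT 2) and 2 from p53fl7KQ/-, Lck-Cre mice (7KQ 1 and 7KQ 2). Replicates are numbered, but nothing states that they came from separate animals or whether animals were pooled, so every p-value measures only the spread between these samples. The libraries were made with droplet-based 3' chemistry that tags each molecule with a unique molecular identifier (UMI).

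The authors' notes list Cell Ranger 2.1.0, Seurat without a version, and the genome build mm10, with no role or order for each. The deposited matrices hold raw UMI counts per gene and cell barcode, 1 matrix per library, with no normalisation. The annotation release, the use of intronic reads and any removal of doublets by the authors are not stated. The feature table lists 27998 genes and holds 0 T cell receptor or immunoglobulin segment genes under the names searched, so receptor clones were not analysed here. The 4 libraries held 9930, 11685, 9497 and 10952 barcodes in the order WT 1, WT 2, 7KQ 1 and 7KQ 2.

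Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Within each library the barcodes with the highest simulated-doublet scores were then removed, 0.8% per 1000 barcodes. That left 36037 of 42064 barcodes. The score came from the scrublet function of scanpy 1.11.5, run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a shared-neighbour graph over 20 neighbours was clustered by the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), over all libraries together and without integration. T and NK clusters were clustered again in the same way.

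Clusters were named from marker lists fixed before the data were examined. A cluster took the name of the class with the most markers found in at least 20% of its cells and at least 3-fold above the other cells, with 3 such markers needed, and a macrophage name needed markers found in 50% of its cells. When T and NK cells were clustered again, names rested on detection alone, with no fold. T names needed Cd3 genes in at least 40% of cells on average, and subset names set shares of cells with Cd8a, Cd8b1, Cd4 or Foxp3. A cluster with Foxp3 in 31.5%, Cd4 in 36.2% and Cd8a in 16.5% of cells got no subset name. These numerical thresholds, and the rules that kept clusters out, were set after the data were seen. Clusters with very low UMI counts stayed unnamed where few of their own markers were among their leading genes. The neutrophil-like and B-like clusters had low counts too (median 0.149 and 0.168 of the library's median) and kept their names. T cell clusters whose macrophage markers were found in 60% of cells on average, and a cluster led by genes of another class, also stayed unnamed. These unnamed clusters held 4.86%, 22.9%, 3.04% and 6.63% of the retained cells of WT 1, WT 2, 7KQ 1 and 7KQ 2. Class names carry "-like" because they rest on transcripts alone.

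UMIs were summed per library and class, since cells are not replicates. Genes were tested in every class with at least 50 cells in every library, with edgeR 4.0.16 quasi-likelihood tests in R 4.3.3, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of 7KQ over WT and levels are CPM, the summed UMIs scaled to a common library total. CD8 T-like cells (2 in WT 1), all T-like cells (18 in WT 1), neutrophil-like cells (38 in 7KQ 1), B-like cells (2 in 7KQ 1), and conventional CD4 and Treg-like cells (0 named) fell short. For CD8 T-like cells WT 2 was therefore compared with both 7KQ libraries, a comparison chosen after the data were seen, in which the lone WT library is assumed to vary like the 7KQ libraries. Fibroblast-like cells were also added after the data were seen. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so the models that pool spread over genes or classes carry the tests.

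Gene lists fixed before the data were examined (22) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. They cover p53 targets, cytotoxic effector genes, exhaustion, naive and memory genes, Treg genes, proliferation, interferon response, antigen presentation and interferon gamma, MHC class II, apoptosis, glycolysis, oxidative phosphorylation, T cell receptor signalling, costimulation, suppressive and inflammatory macrophage genes, stress, and markers of other cells (macrophage, neutrophil, T, B, and tumour and stroma). T cell lists were tested in lymphoid classes and macrophage lists in the others, and a list with too few measured members was not tested. The difference in genotype effect between classes was tested as the class-by-genotype term of 1 model with library as a block. Cell numbers per class were tested with edgeR quasi-likelihood tests with the log of the retained cells of the library as offset. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

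Genes named in every class were Trp53, Cdkn1a, Mdm2, Ccng1, Zmat3, Pdcd1, Gzmb, Ifng, Tcf7, Foxp3, Cd274 and Mki67. Beyond these, called genes with a mean of at least 20 CPM and no overlap between genotypes were named, up to 10 per direction in T cell classes and 6 in the others. Mitochondrial and predicted genes were left out of that pick. Where fewer than 5 genes were called, the 6 with the smallest p are named as values. Called members of the lists may be named as well, and members that were not called serve as examples chosen after their values were seen. Some genes that meet this rule are not reported here. The lists and this rule were fixed before the data were examined.

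Genes that share reads with near-identical copies were found with BLAST 2.17.0, a search added after the data were seen. The last 500 nucleotides of the longest transcript of 15586 genes were searched against all mouse transcripts of the annotation, and 915 genes (5.87%) had a match of at least 90 nucleotides at 97% identity in another gene. Alternatives were DESeq2 1.42.0 for the test and its size factors, no filter on low counts, doublets kept, a stricter filter (500 genes and 5% mitochondrial UMIs), genes scaled within each library before clustering, resolution 2, classes gated by marker UMIs, TMM factors over classes, replicate number as a block, and each library left out in turn. Genes with near-identical copies were left out in a further alternative chosen after the data were seen.

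The fits were tested on simulated data with the observed spread, taken as the common dispersion of each fit for every gene. Spread particular to a gene and a shift of a whole library, such as WT 1, were not simulated. Recovery in the real data may therefore be lower than given here. Of 50 genes changed 4-fold, the edgeR test recovered 84% in NK-like, 96% in macrophage-like, 92% in dendritic-like and 96% in fibroblast-like cells, and 74% in CD8 T-like cells with 1 WT library. At 2-fold it recovered 20% to 28%, with 2 to 10 false calls per fit. For the T against macrophage term 50% of 4-fold changes were recovered, and for the NK against macrophage term 64%. A 4-fold change in the share of CD8 T-like cells was called in 9 of 100 simulations at the observed dispersion of 0.504.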

Results

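Cd45+ cells, which are leukocytes by their surface marker, were profiled from MC38 tumours in mice of 2 genotypes, with 2 libraries each. Both genotypes carry Lck-Cre, a Cre recombinase expressed in the T cell lineage, and a null allele of p53. The other allele is wild type in the group labelled WT and the fl7KQ allele in the group labelled 7KQ, whose name stands for lysine-to-glutamine changes. The labels do not state whether the genotypes share 1 mouse substrain, so a difference of background is not separated from the p53 allele in any comparison. The comparison asks which infiltrating cells and which of their transcripts differ between tumours of the 2 genotypes. Total counts were 141636143 UMIs in WT 1, 109168579 in WT 2, 144585105 in 7KQ 1 and 141576822 in 7KQ 2. WT 2 was the shallowest per barcode, with a median of 9362 UMIs against 13634, 14915 and 12586 in WT 1, 7KQ 1 and 7KQ 2. Filters kept 8101, 10264, 8184 and 9488 cells of WT 1, WT 2, 7KQ 1 and 7KQ 2.

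Macrophage-like cells made up most of every library, and CD8 T-like cells, the killer T cells, were nearly missing from 1 of the WT tumour libraries. WT 1 held 2 CD8 T-like cells, a share of 0.0247% (95% interval 0.00299 to 0.0892%). That number depends on the clustering: with genes scaled within each library WT 1 held 50 (236, 273 and 591 in WT 2, 7KQ 1 and 7KQ 2) while its NK-like cells went from 89 to 41, and all retained cells of WT 1 held 14 UMIs of Cd8a, which encodes a chain of CD8. Of all 9930 deposited WT 1 barcodes, 4 held 2 Cd3 UMIs and a Cd8a or Cd8b1 UMI, so most of the 50 do not meet such a gate. In the main setting WT 2 held 242 (2.36%, 2.07 to 2.67%), 7KQ 1 held 282 (3.45%, 3.06 to 3.86%) and 7KQ 2 held 613 (6.46%, 5.97 to 6.97%). Both 7KQ libraries thus held a larger CD8 share than both WT libraries. All T-like cells numbered 18, 293, 346 and 662 in WT 1, WT 2, 7KQ 1 and 7KQ 2. Further T cells lay in 2 clusters that also carried macrophage transcripts and were kept out of the class, with 3, 42, 68 and 302 cells together. B-like cells numbered 36 in WT 1 and 3, 2 and 2 in WT 2, 7KQ 1 and 7KQ 2. Dendritic-like cells took 3.97% of WT 1 and 2.51%, 2.07% and 2.33% of WT 2, 7KQ 1 and 7KQ 2. NK-like cells lay between 1.10% and 1.74% of each library, neutrophil-like cells between 0.464% and 0.889%, and fibroblast-like cells, present despite the Cd45 sort, between 1.04% and 1.57%. Whether fibroblast-like cells were host cells or injected tumour cells was not tested, and the genotypes are those of the mice. Macrophage-like cells took 87.5% and 68.2% of WT 1 and WT 2 and 87.1% and 80.4% of 7KQ 1 and 7KQ 2. In WT 2, the library with the lowest depth, 21.9% of cells lay in unnamed clusters with very low UMI counts, against 2.74%, 2.16% and 3.39% in WT 1, 7KQ 1 and 7KQ 2. Every share counts these cells in its total, which lowers the shares of the named classes in WT 2. Part of the gap in CD8 share between WT 2 and 7KQ 1 comes from this.

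**Figure D1:**
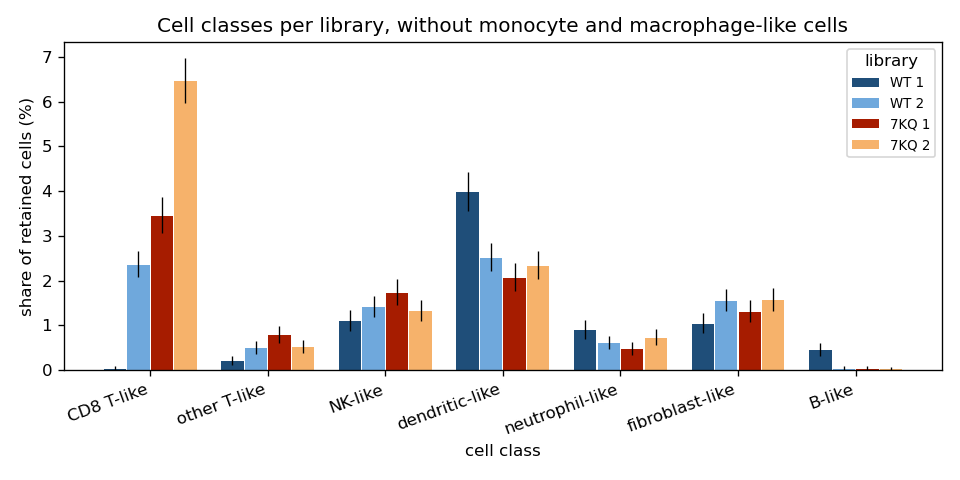
Share of retained cells (%) per cell class and library, without macrophage-like cells, with exact 95% intervals as lines. CD8 T-like cells take 0.0247% of WT 1, 2.36% of WT 2, 3.45% of 7KQ 1 and 6.46% of 7KQ 2.

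None of the 9 shares, the unnamed cells included, passed the edgeR test between genotypes (smallest adjusted p = 0.59; 0 shares passed at an unadjusted p under 0.05). For CD8 T-like cells the log2 fold change was 2.05 (SE 1.85, n = 2 per genotype; adjusted p = 0.59). Without WT 2, CD8 T-like cells were higher in 7KQ by 7.57 on the log2 scale (adjusted p = 1.1e-04) and B-like cells fell by 4.21, so 2 shares passed. Without WT 1, 1 share passed, that of the unnamed cells, and the CD8 T-like change was 1.07 (SE 0.52; adjusted p = 0.31). Among T-like cells, CD8 T-like cells were 2 of 18 in WT 1 and 82.6%, 81.5% and 92.6% in WT 2, 7KQ 1 and 7KQ 2. Neither T cell class changed its share of T-like cells (adjusted p = 0.55 for CD8 T-like and 0.43 for other T-like cells).

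Trp53, which encodes p53, did not pass the test in any class. In macrophage-like cells it stood at 25.4 and 25.8 CPM (UMI counts per library scaled to a common total) in WT 1 and WT 2 and 27.0 and 23.4 in 7KQ 1 and 7KQ 2. In CD8 T-like cells it stood at 51.3 in WT 2 and 34.4 and 33.7 in 7KQ (-0.62, SE 0.30; adjusted p = 0.59), and in fibroblast-like cells at 139.6 and 140.5 in WT and 186 and 168 in 7KQ (0.22, SE 0.21; adjusted p = 0.83). 3' tags of a point-mutated allele are counted like those of the wild-type allele, and each genotype carries a null allele, so these levels do not check the genotype labels. The labels do not state in which cells the fl7KQ allele was recombined, and this was not tested. Lck-Cre is expressed in the T cell lineage, so differences in the other classes are no measure of mutated p53 within those cells. Cdkn1a and Mdm2, a cell cycle inhibitor and the main negative regulator of p53, are the best known p53 targets. Cdkn1a stood at 569 and 557 CPM in WT macrophage-like cells and 934 and 745 in 7KQ (log2 fold change 0.59, SE 0.24; adjusted p = 0.44). Mdm2 stood at 53.2 and 60.2 in WT and 105 and 108 in 7KQ (0.92, SE 0.14; adjusted p = 0.30). In dendritic-like cells Cdkn1a stood at 430 and 457 in WT and 781 and 686 in 7KQ, and Mdm2 at 23.5 and 29.4 in WT and 55.3 and 53.8 in 7KQ. Neither gene passed the edgeR test over all genes in any of the classes tested. Without WT 2 Mdm2 in monocyte and macrophage-like cells passed (adjusted p = 0.0082), as did Mdm2 in dendritic-like cells (adjusted p = 0.0048). DESeq2 called it in the former (adjusted p = 1.3e-04) and not in the latter (adjusted p = 0.48). In NK-like cells Cdkn1a stood at 90.7 and 54.1 in WT and 56.4 and 75.3 in 7KQ, and Mdm2 at 32.1 and 34.6 in WT and 32.8 and 28.1 in 7KQ.

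The list of p53 targets did not move as a group in any class. Of 35 measured members in macrophage-like cells 13 were higher and 22 lower in 7KQ (median log2 fold change -0.06; adjusted p = 0.87). Adjusted over the list alone, 1 of the 35 passed, Mdm2. In dendritic-like cells 17 of 26 members were higher (median 0.11; adjusted p = 0.31), in NK-like cells 9 of 24 (median -0.10; adjusted p = 0.50) and in fibroblast-like cells 17 of 29 (median 0.20; adjusted p = 0.16). Ccng1 and Zmat3, further targets, differed in macrophage-like cells by 0.12 and 0.08 on the log2 scale (SE 0.15 and 0.19).

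**Figure D2:**
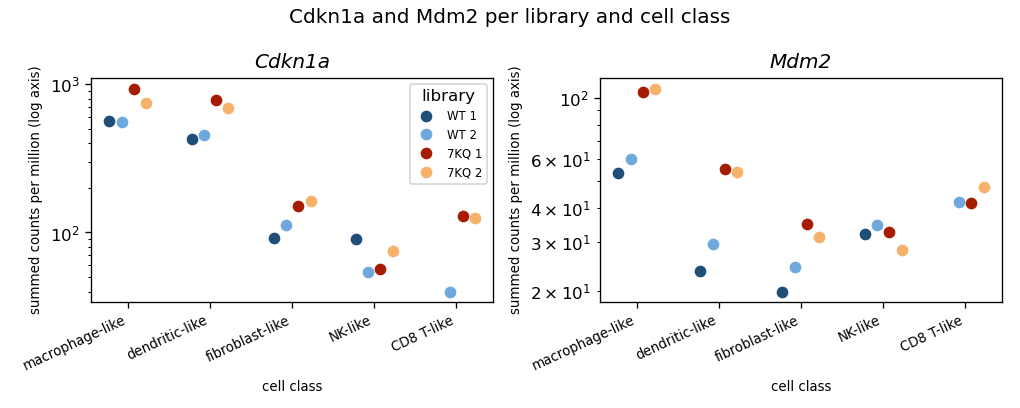
Cdkn1a and Mdm2 in CPM of summed UMIs (log axis) per library and cell class, with a point per library. Macrophage-like cells reach 934 and 745 for Cdkn1a in 7KQ against 569 and 557 in WT, and CD8 T-like cells, with 2 cells in WT 1 and no point for it, reach 130 and 126 in 7KQ against 39.9 in WT 2.

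CD8 T-like cells of both 7KQ libraries held about the same high Cdkn1a level, above that of WT 2. Cdkn1a stood at 39.9 CPM in WT 2 (74 UMIs), 130 in 7KQ 1 and 126 in 7KQ 2, a log2 fold change of 1.65 (SE 0.34, n = 1 against 2), with an adjusted p of 0.12 over all genes. Mdm2 stood at 42.1, 41.7 and 47.7, and 20 of the 33 measured p53 targets were higher in 7KQ (median 0.08; adjusted p = 0.60). Adjusted over the list alone, 1 of the 33 passed, Cdkn1a. Genes of killer function and exhaustion did not move as groups: Gzmb, a granzyme that kills target cells, stood at 580, 805 and 752, Pdcd1, the receptor PD-1, at 584, 448 and 575, and Ifng, which encodes interferon gamma, at 201, 137 and 206 in WT 2, 7KQ 1 and 7KQ 2. The interferon response list rose in 7KQ (15 of 19 members higher, median 0.60; adjusted p = 4.0e-04, and 0.98 with an estimated correlation), with Isg15 at 8.10, 21.3 and 31.2 and Bst2 at 23.8, 60.8 and 44.4. Glycolysis genes rose (14 of 15 higher, median 0.43; adjusted p = 0.0025), with Pkm at 391, 631 and 585, and so did costimulatory receptors (6 of 7 higher, median 0.39; adjusted p = 0.020), with Icos at 236, 471 and 624. Neither held (adjusted p = 0.98 with an estimated correlation for both). The antigen presentation list had 16 of 24 members higher (adjusted p = 0.11), proliferation 14 of 28 (adjusted p = 0.87), and the other-cell macrophage list 9 of 15 (adjusted p = 0.87). The remaining lists tested, cytotoxic effector, exhaustion, naive and memory, Treg genes, apoptosis, oxidative phosphorylation, T cell receptor signalling, stress and tumour and stroma, had adjusted p between 0.38 and 0.96. Median and test direction differed in sign for the cytotoxic effector, exhaustion, proliferation and T cell receptor signalling lists, and median and mean for Treg genes.

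Of 9915 genes tested in CD8 T-like cells, 15 passed, 2 higher and 13 lower in 7KQ, and 857 had an unadjusted p under 0.05. Of the 15, 8 share reads with near-identical copies, among them Hist1h2ap (-3.17), Hist1h3b (-2.17), Polr2l (-1.82) and Grcc10 (-1.73), so which gene those reads come from is uncertain. Dgat1, an enzyme of triglyceride synthesis, stood at 24.8 in WT 2 and 113 and 101 in 7KQ (2.08, SE 0.36; adjusted p = 0.034). Cd55, an inhibitor of complement, fell from 54.0 to 13 and 10.4 (-2.24, SE 0.33; adjusted p = 0.020). The largest cluster of CD8 T-like cells differed between the libraries: cluster 3 held 64.5% of those of WT 2, clusters 5 and 1 held 40.4% and 37.2% of those of 7KQ 1, and cluster 0 held 52.2% of those of 7KQ 2. Cluster 1 also held 25.6% of those of WT 2 and 23.5% of those of 7KQ 2. With doublets kept, with genes scaled within each library, or with copied genes left out, edgeR called 0 genes (796, 797 and 746 at an unadjusted p under 0.05), and DESeq2 called 10 in the main setting. Marker gating gave 2 genes, the stricter filter 26, and no filter on low counts 71.

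Macrophage-like cells of 7KQ tumours carried more transcripts of antigen presentation and interferon response. For antigen presentation most of the difference lay between WT 1 and the other 3 libraries, while interferon response genes varied: Bst2 stood at 107 and 126 CPM in WT and 248 and 252 in 7KQ, and Irf7 at 12.4 and 37.4 in WT and 38.0 and 52.4 in 7KQ. The antigen presentation list, genes that load and show peptides on MHC class I together with interferon gamma targets, rose with 24 of 24 members higher in 7KQ (median 1.09; adjusted p = 2.8e-11, and 0.47 with an estimated correlation). Cxcl9, a chemokine induced by interferon gamma, stood at 21.6 and 1049 CPM in WT 1 and WT 2 and at 1130 and 1365 in 7KQ 1 and 7KQ 2. Cd274, which encodes PD-L1, stood at 26.3 and 116 in WT and 156 and 211 in 7KQ, and H2-K1 at 453 and 1511 in WT and 1447 and 2172 in 7KQ. Every one of the 24 members was lowest in WT 1, with a median log2 difference of 2.12 between WT 2 and WT 1 and 0.39 between 7KQ and WT 2. The interferon response list rose (26 of 27 higher, median 0.68; adjusted p = 1.3e-10), as did MHC class II genes (7 of 7 higher, median 0.91; adjusted p = 0.0033) and inflammatory macrophage genes (17 of 18 higher, median 0.89; adjusted p = 3.3e-08), each with adjusted p = 0.47 with an estimated correlation. Of the class II genes, H2-Ab1 stood at 398 and 3280 in WT and 3347 and 3432 in 7KQ, and Cd74 at 1222 and 7145 in WT and 8740 and 8202 in 7KQ, so WT 1 stood apart. Of the inflammatory genes, Nos2, the inducible nitric oxide synthase, stood at 12.2 and 33.6 in WT and 93.6 and 123 in 7KQ, and Il1b at 556 and 1075 in WT and 1735 and 1290 in 7KQ. Glycolysis (13 of 15 higher; adjusted p = 0.0070) and apoptosis genes (16 of 21 higher; adjusted p = 0.024) rose too, both with adjusted p = 0.47 with an estimated correlation. Proliferation genes fell, 25 of 28 lower in 7KQ (median -0.39; adjusted p = 1.6e-04, and 0.47 with an estimated correlation), with Top2a at 320 and 329 in WT and 231 and 241 in 7KQ. Markers of T cells rose in these cells as well (6 of 6 higher, median 1.10; adjusted p = 0.0023, and 0.47 with an estimated correlation).

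The suppressive macrophage list did not pass in macrophage-like cells (13 of 20 higher; adjusted p = 0.31), and its median of 0.34 and mean of -0.12 differ in sign. Its member Arg1, an arginase, stood at 1256 and 1066 in WT and 1960 and 2021 in 7KQ. Oxidative phosphorylation, stress and the neutrophil, B and tumour and stroma markers had adjusted p between 0.069 and 0.25. Of 13855 genes tested, 0 passed with edgeR (1596 at an unadjusted p under 0.05), while DESeq2 called 390. Levels did not overlap between genotypes for 45.2% of the genes, against 33.3% expected by chance. The share was 42.3% in dendritic-like, 41.8% in fibroblast-like and 28.4% in NK-like cells. Genes of a library can move together, so a share above 33.3% is no measure of a genotype effect. The genes with the smallest p were Tmeff1 (2.52), Gzmg (2.15), Msantd3 (2.30), Rpl27-ps3 (-2.28), Nnt (-1.26) and Hist1h4a (-2.01), of which Rpl27-ps3, Nnt and Hist1h4a share reads with near-identical copies. Gzmg in monocyte and macrophage-like cells was -0.53 with marker gating. Macrophage-like cells of WT 1, of WT 2 and of the 7KQ libraries lay mostly in different clusters. Clusters 2, 3 and 9 held 94.6% of those of WT 1, and clusters 4 and 8 held 66.6% of those of WT 2. Clusters 0, 1 and 6 held 71.3% and 71.0% of those of 7KQ 1 and 7KQ 2. Cluster 7 was shared, with 10.9%, 13.3% and 10.1% of those of WT 2, 7KQ 1 and 7KQ 2. Without WT 1 106 genes passed and without WT 2 1434, while without either 7KQ library 0 passed.

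**Figure D3:**
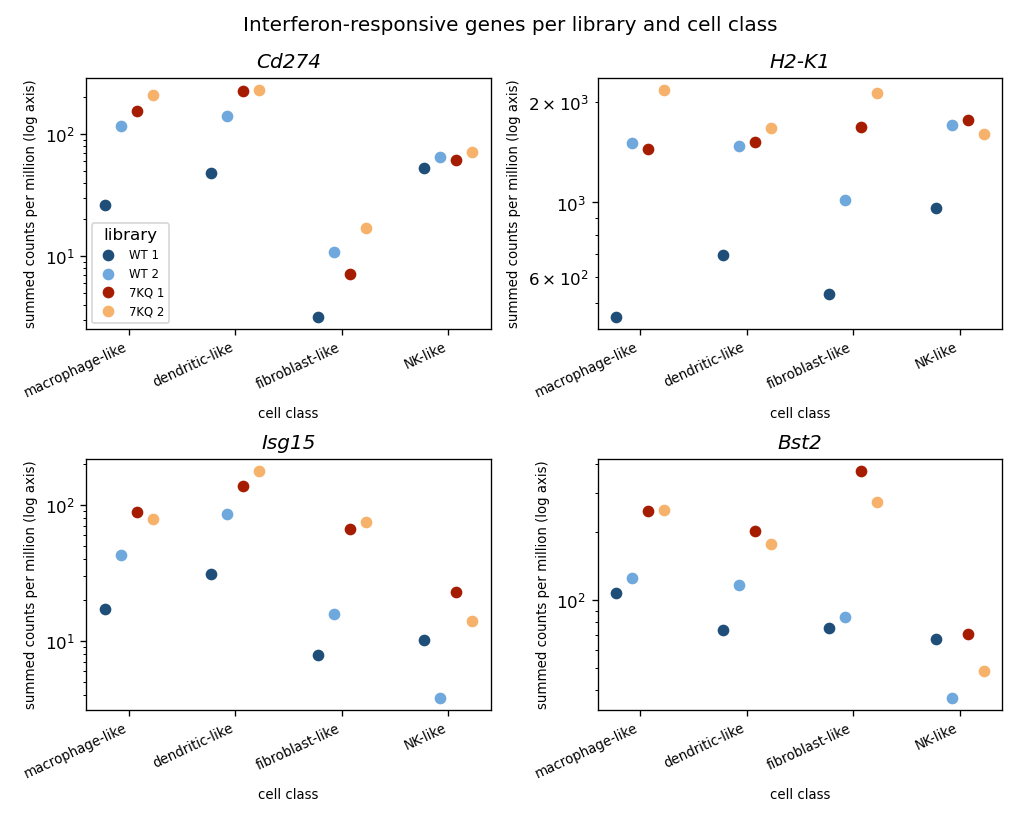
Cd274, H2-K1, Isg15 and Bst2 in CPM of summed UMIs (log axis) per library and cell class, with a point per library. In macrophage-like cells Cd274 lies at 26.3 in WT 1, 116 in WT 2, 156 in 7KQ 1 and 211 in 7KQ 2.

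Dendritic-like cells, which present antigen to T cells, carried more class I and interferon transcripts in 7KQ tumours, while their class II genes did not pass. The antigen presentation list rose with 24 of 24 members higher in 7KQ (median 1.22; adjusted p = 1.1e-17), each lowest in WT 1 (median difference 1.63 between WT 2 and WT 1 and 0.44 between 7KQ and WT 2), and the interferon response list with 23 of 26 (median 0.73; adjusted p = 4.1e-07), both with adjusted p = 0.69 with an estimated correlation. Psmb8, an immunoproteasome subunit, stood at 351 and 607 in WT and 911 and 976 in 7KQ, and Cxcl9 at 18.8 and 964 in WT and 1391 and 1154 in 7KQ. MHC class II genes showed no such shift (2 of 7 higher, median -0.04; adjusted p = 0.98), with H2-Ab1 at 7718 and 7276 in WT and 7530 and 8355 in 7KQ. Whether the class II list differs between dendritic-like and macrophage-like cells was not tested. Stress genes fell (15 of 20 lower, median -0.40; adjusted p = 4.5e-04), with Fos at 662 and 459 in WT and 287 and 357 in 7KQ, and proliferation genes fell (20 of 28 lower, median -0.28; adjusted p = 0.014). Neither held (adjusted p = 0.69 with an estimated correlation for both). Apoptosis, glycolysis, oxidative phosphorylation, suppressive and inflammatory macrophage genes and macrophage markers had adjusted p between 0.11 and 0.95. For the oxidative phosphorylation and inflammatory lists the median and the mean differed in sign. Of 9232 genes 0 passed with edgeR (878 at an unadjusted p under 0.05), and DESeq2 called 43. Among the genes with the smallest p were Hist1h3b (-2.39), Cx3cr1 (-2.19), Hist1h2ap (-3.79), Pdcd4 (-1.93) and Dynlt1b (-3.44), of which all but Cx3cr1, a chemokine receptor, and Pdcd4 share reads with near-identical copies. Without WT 1 119 genes passed and without WT 2 866, while no filter on low counts gave 372 and the replicate block 41.

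NK-like cells, innate killer cells, carried Gzmc, a granzyme, at 14841 and 12200 CPM in WT and 12733 and 12936 in 7KQ. Gzmb stood at 830 and 709 in WT and 912 and 1385 in 7KQ (0.51, SE 0.36; adjusted p = 1.00). The cytotoxic effector list rose (17 of 22 higher, median 0.30; adjusted p = 0.0039, and 0.32 with an estimated correlation), with Gzma at 786 and 808 in WT and 1633 and 1006 in 7KQ. Antigen presentation genes rose by less than in macrophage-like cells (19 of 23 higher, median 0.32; adjusted p = 2.5e-05, and 0.38 with an estimated correlation), a difference between classes that was not tested. Of the 23 members 18 were lowest in WT 1, with a median difference of 0.73 between WT 2 and WT 1 and 0.11 between 7KQ and WT 2. Naive and memory genes (10 of 11 higher; adjusted p = 0.0011), costimulatory receptors (5 of 6 higher; adjusted p = 0.0036), exhaustion genes (12 of 16 higher; adjusted p = 0.030) and interferon response genes (9 of 12 higher; adjusted p = 0.012) rose. None of these held (adjusted p = 0.32, 0.32, 0.38 and 0.50 with an estimated correlation). Glycolysis genes fell, 15 of 15 lower in 7KQ (median -0.28; adjusted p = 0.0041), with Ldha at 1018 and 578 in WT and 623 and 511 in 7KQ, and so did oxidative phosphorylation genes (20 of 25 lower; adjusted p = 0.012), with adjusted p = 0.61 and 0.63 with an estimated correlation. Without WT 1 both turned up, with adjusted p = 0.655 for the glycolysis list in NK-like cells and 0.516 for the oxidative phosphorylation list in NK-like cells. Markers of T cells (4 of 4 higher, median 1.09; adjusted p = 3.0e-06) and of macrophages (12 of 15 higher; adjusted p = 0.019) rose in the same cells, with adjusted p = 0.32 and 0.61 with an estimated correlation. Proliferation, Treg genes, apoptosis, T cell receptor signalling and stress had adjusted p between 0.058 and 0.77, and the apoptosis median and mean differed in sign. Without WT 1 3 lists passed in place of 10.

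Of 7866 genes tested in NK-like cells 1 passed, Hist1h2ap, a histone gene (-3.17, SE 0.39; adjusted p = 0.046), which shares reads with near-identical copies, and 306 had an unadjusted p under 0.05. Rora, a transcription factor of lymphoid cells, stood at 21.9 and 23.3 in WT and 81.3 and 81.9 in 7KQ (1.80, SE 0.28; adjusted p = 0.096). Ccl1, a chemokine, stood at 275 and 82.6 in WT and 16.4 and 3.69 in 7KQ (-4.24, SE 0.69; adjusted p = 0.096). Grcc10 (-2.35) and Polr2l (-1.92), which also share reads with copies, were among the genes with the smallest p. The count was 0 with doublets kept, with the stricter filter and with copied genes left out (306, 311 and 265 at an unadjusted p under 0.05), 8 with DESeq2, 45 with no filter on low counts and 97 with the replicate block. Leaving out WT 1, WT 2, 7KQ 1 or 7KQ 2 gave 3, 16, 24 and 18 genes.

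Fibroblast-like cells, not separated here into host and injected tumour cells, carried more interferon response transcripts in 7KQ tumours, with single genes called in the main setting. The interferon response list rose with 22 of 22 members higher in 7KQ (median 1.64; adjusted p = 3.2e-38, and 0.32 with an estimated correlation), 3 of them called over all genes and 17 adjusted over the list alone. Isg15 stood at 7.84 and 15.7 in WT and 67.3 and 74.6 in 7KQ (2.44, SE 0.29; adjusted p = 0.033), Bst2 at 75.3 and 84.4 in WT and 375 and 273 in 7KQ (1.90, SE 0.24; adjusted p = 0.035), and Ifit3 rose by 4.01 (SE 0.52; adjusted p = 0.035). With doublets kept no gene was called as higher, with adjusted p = 0.062 for Isg15 in fibroblast-like cells (2.77) and 0.070 for Bst2 in fibroblast-like cells (1.91). The antigen presentation list rose with 24 of 24 members higher (median 1.41; adjusted p = 2.8e-34, and 0.38 with an estimated correlation), 0 of them called over all genes and 19 adjusted over the list alone. All 24 were lowest in WT 1, with a median difference of 1.51 between WT 2 and WT 1 and 1.01 between 7KQ and WT 2. H2-T22, a class I gene outside the lists, rose from 25.6 and 30.2 to 86.6 and 107 (1.68, SE 0.23; adjusted p = 0.035). MHC class II genes rose (6 of 6 higher; adjusted p = 2.2e-05, and 0.38 with an estimated correlation), with WT 1 apart: H2-Ab1 stood at 21.4 and 331 in WT and 295 and 240 in 7KQ, and Cd74 at 29.8 and 538 in WT and 605 and 514 in 7KQ. Macrophage markers stood in these cells at a median of 0.0538 and 0.0752 of their macrophage level in WT 1 and WT 2 and 0.0430 and 0.0378 in 7KQ 1 and 7KQ 2, so these class II levels are not separated from free RNA of macrophages. In contrast, suppressive macrophage genes (13 of 14 lower; adjusted p = 0.0038) and macrophage markers (12 of 15 lower; adjusted p = 0.0038) fell. Neither held (adjusted p = 0.38 with an estimated correlation for both). Without WT 2 the macrophage markers rose (adjusted p = 0.0030). Cdkn1a stood at 92.0 and 113 in WT and 150.1 and 162 in 7KQ (0.49, SE 0.21; adjusted p = 0.57). Proliferation, apoptosis, glycolysis, oxidative phosphorylation, inflammatory macrophage and stress genes had adjusted p between 0.16 and 0.80, and the glycolysis median and mean differed in sign.

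In fibroblast-like cells 11 of 10239 genes passed, 5 higher and 6 lower in 7KQ, and 880 had an unadjusted p under 0.05. Those lower included Igfbp3 (-6.41), Sparcl1 (-5.07) and Fabp4 (-3.22), below the level set for naming and given because they were called, with Hist1h4h (-2.03) and Gm10073 (-4.50). The fifth of those higher was Apol9b (2.32). Gm10073 and Apol9b share reads with near-identical copies. The count was 245 without WT 1, 233 without WT 2, 94 without 7KQ 2, 194 with the replicate block, 73 with DESeq2, 325 with no filter on low counts and 2 with doublets kept, 0 of them higher.

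The genotype effect was compared between T-like and macrophage-like cells of the same libraries, since Lck-Cre acts in T cells. The genotype effect was lower in T-like than in macrophage-like cells for the granzymes Gzma (-3.18, SE 0.41), Gzmd (-2.09, SE 0.30) and Gzme (-2.10, SE 0.30), for Ly6a (-3.36, SE 0.54), a surface marker of activated lymphocytes, and for Il7r (-1.96, SE 0.38), the receptor of interleukin 7, whose reads are shared with a near-identical copy and so are uncertain. The term does not say which class moved. In macrophage-like cells Gzma stood at trace levels, 0.396 and 0.382 in WT and 2.92 and 0.780 in 7KQ (2.28, SE 0.70), and Ly6a at 7.98 and 285 in WT and 484 and 624 in 7KQ. In CD8 T-like cells Gzma stood at 91.2 in WT 2 and 37.2 and 18.4 in 7KQ, while Ly6a was higher in 7KQ, at 116 in WT 2 and 259 and 270.5 in 7KQ. Of 13535 genes 36 passed, 14 higher and 22 lower (590 at an unadjusted p under 0.05), and WT 1 enters with 18 T-like cells. Cdkn1a (0.93, SE 0.48) and Mdm2 (-0.63, SE 0.34) did not pass over all genes or adjusted over the list alone. The p53 target list did not pass either (unadjusted camera p = 0.15, and 0.32 with an estimated correlation). DESeq2 called 0 genes (102 at an unadjusted p under 0.05), and 0 passed with genes scaled within each library (782). The count was 69 without WT 1, 292 without WT 2, 6 without 7KQ 1, 3 without 7KQ 2, 66 with marker gating and 12 with the replicate block.

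The same term for NK-like against macrophage-like cells, added after the data were seen, gave 11 of 13391 genes, 7 higher and 4 lower (660 at an unadjusted p under 0.05). The genotype effect was higher in NK-like than in macrophage-like cells for Tmem176b (2.55, SE 0.32) and Tmem176a (2.09, SE 0.30), which encode membrane proteins, and for Rora (1.52, SE 0.29), and lower for Ccl1 (-3.62, SE 0.52) and Upp1 (-3.26, SE 0.59), a uridine phosphorylase. In macrophage-like cells Tmem176b stood at 80.6 and 102 in WT and 37.7 and 22.0 in 7KQ, and Upp1 at 2.58 and 18.1 in WT and 47.7 and 59.3 in 7KQ. Mdm2 differed by -1.06 (SE 0.28; adjusted p = 0.26 over all genes and 0.034 adjusted over the list alone). DESeq2 called 5 genes. The count was 293 without WT 2, 61 without 7KQ 1, 56 without 7KQ 2, 142 with the replicate block, 116 with no filter on low counts, 59 with marker gating, 55 with the stricter filter, 4 with genes scaled within each library and 6 with copied genes left out.

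Positions are those of mm10. Trp53 (ENSMUSG00000059552) lies on chromosome 11 from 69580359 to 69591873, Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727, and Mdm2 (ENSMUSG00000020184) on chromosome 10 from 117688875 to 117710758. Hist1h2ap (ENSMUSG00000094777) lies on chromosome 13 from 21833026 to 21833507, Dgat1 (ENSMUSG00000022555) on chromosome 15 from 76502015 to 76511953, Isg15 (ENSMUSG00000035692) on chromosome 4 from 156199424 to 156200818, and Bst2 (ENSMUSG00000046718) on chromosome 8 from 71534255 to 71537456. Rora (ENSMUSG00000032238) lies on chromosome 9 from 68653786 to 69388246 and Gzma (ENSMUSG00000023132) on chromosome 13 from 113093825 to 113100981. All are annotated as protein-coding genes.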

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

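Of the tests in this part, both tests on short transcripts, the test on genotype, and the tests on a shared Cdkn1a rise and on p53 activity were chosen only after the result was seen.

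The genotype effect differed between T-like and macrophage-like cells for 36 genes, by the class-by-genotype term of the model. The 4 with the smallest p were Gzma (-3.18), Gzmd (-2.09), Gzme (-2.10) and Ly6a (-3.36), each with a lower genotype effect in T-like than in macrophage-like cells. Gzma differed by 2.28 (SE 0.70) in macrophage-like cells, at trace levels, so the term is no measure of a fall within T cells. WT 1 enters this comparison with 18 T-like cells, of which 2 are CD8 T-like, against 82.6%, 81.5% and 92.6% CD8 T-like cells in WT 2, 7KQ 1 and 7KQ 2, so a different mix of T cells is not separated from a change within them. Between NK-like and macrophage-like cells the effect differed for 11 genes by the same test, led by Tmem176b (2.55), Tmem176a (2.09), Ccl1 (-3.62) and Upp1 (-3.26). DESeq2 called 0 genes for the T-like term (102 at an unadjusted p under 0.05) and 5 for the NK-like term.

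The first pattern is a set of 24 genes of 7183, among them Hist1h2ap, Polr2l and Grcc10, that were lower in both 7KQ libraries by more than 1 on the log2 scale in macrophage-, dendritic-, NK- and fibroblast-like cells alike (3 were higher by the same rule, Gm11808, Igtp and Isg15). Free RNA of macrophages is argued against. These genes stood in the other classes at 1.08 times their macrophage level or more (median, WT libraries). For the 14 longer genes loss of short transcripts is not decided, since length was that of the longest annotated transcript, which may not be the one measured. Other genes over their whole length range had a median of -0.017 at the lowest. In the shortest part of that range, where most of the 14 lie, the macrophage-like median was -0.10, the lowest of the classes. There 10.4% of genes were lower by more than 1, against 3.24% of the longest genes. A loss of that size common to most genes of their annotated length is thus argued against. For the 10 shortest genes loss of short transcripts cannot be told apart from other causes, since other genes that short had a median of -0.40 in the class with the least negative value, between the bounds set. Reads shared with near-identical copies are a candidate explanation: 91.7% of the 24 genes (22, 95% interval 73.0 to 99.0%) have such a copy against 5.68% of the others (Fisher's exact p = 1.7e-25), although other genes with copies had medians between -0.07 and 0.02. A difference in mapping or annotation between the libraries of the 2 genotypes would lie along the same line as genotype, which stays open as untested.

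The second pattern is WT 1, with 2 CD8 T-like cells and the lowest level of all 24 antigen presentation genes in macrophage-like cells. With genes scaled within each library 50 cells of WT 1 took the CD8 T-like name, though 4 of its deposited barcodes lay in a CD8 T cell gate. Removal of CD8 T cells by the filters is argued against, since 0 of the filtered-out WT 1 barcodes lay in a CD8 T cell gate. WT 1 and WT 2 carry the same genotype label, so genotype alone does not give the median log2 difference of 2.12 between them for the antigen presentation genes. In WT 2 macrophage-like cells 100% of the list lay nearer to 7KQ than to WT 1. The pattern was picked from these same values, so that share is no separate evidence. In dendritic-, NK- and fibroblast-like cells 23 of 24, 18 of 23 and 17 of 24 genes lay nearer to 7KQ. How much genotype adds was not tested. Less interferon gamma from fewer CD8 T cells stays a candidate that the test cannot decide. Ifng in WT 1 was 0.0130 times the lowest other library, with 8 UMIs against 587, 636 and 1295. In WT 2, Ifng stood at 201 CPM in CD8 T-like and 0.405 in macrophage-like cells. A library with few CD8 T-like cells thus holds little Ifng in any case. In NK-like cells Ifng stood at 4.69 in WT 1 and 28.5, 17.7 and 25.1 in WT 2, 7KQ 1 and 7KQ 2. What made CD8 T-like cells few in WT 1 was not tested.

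The third pattern is the level of Cdkn1a in 7KQ CD8 T-like cells, 130 and 126 CPM against 39.9 in WT 2. Free RNA of macrophages is argued against, since it gives at most 23.3% of that level in a 7KQ library (18.6 CPM, or 46.5%, in WT 2, and 23.7 and 29.3 CPM in 7KQ 1 and 7KQ 2). A rise shared by the other classes is argued against as the whole change, but only weakly. The log2 change lies 1.02 (SE 0.42) above that of dendritic-like cells, the highest of the others. That SE treats the classes as independent, and the CD8 T-like value uses WT 2 alone while the dendritic-like value uses both WT libraries. With library as a block, the term for T-like against macrophage-like cells was 0.93 (SE 0.48) and did not pass. No rise common to the other p53 targets was seen: the other 32 had a median of 0.072 (SE 0.079), 19 higher and 13 lower. The rule set for arguing against higher p53 activity also asked that the members move one way. Targets that do not respond would not do so, and the test could not decide against it. Higher p53 activity that moves few targets cannot be told apart from a change of Cdkn1a alone. With a single WT library holding CD8 T-like cells in number, a difference of WT 2 alone stays open, as does genotype, which was not tested separately. Cluster 3 held 64.5% of the CD8 T-like cells of WT 2, against 3.90% and 18.8% of those of 7KQ 1 and 7KQ 2. A different mix of CD8 T-like cells is thus not separated from a change within them.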

How the results depend on the processing

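The comparison of CD8 T-like cells, the fibroblast-like class, the NK-like against macrophage-like term and leaving out genes with near-identical copies were chosen after seeing the data. Where a library was left out, the lone library of its genotype is assumed to vary like the others. Except where fewer genes or libraries were tested, the cause was not tested for any difference below.

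The DESeq2 test called 8 genes in NK-like (1 in the main analysis), 390 in macrophage-like (0), 43 in dendritic-like (0) and 73 in fibroblast-like cells (11), 0 for the T-like term (36) and 5 for the NK-like term (11). With no filter on low counts the numbers were 45 in NK-like, 1 in macrophage-like, 372 in dendritic-like, 325 in fibroblast-like and 71 in CD8 T-like cells (15), and 116 for the NK-like term. With doublets kept they were 0 in NK-like, 2 in fibroblast-like and 0 in CD8 T-like cells. The stricter filter gave 0 in NK-like and 26 in CD8 T-like cells and 55 for the NK-like term. Scaling genes within each library gave 0 in CD8 T-like cells, 0 for the T-like term and 4 for the NK-like term. Marker gating gave 2 in CD8 T-like cells, 66 for the T-like term and 59 for the NK-like term. Leaving out genes with near-identical copies gave 0 in NK-like and 0 in CD8 T-like cells and 6 for the NK-like term. With replicate number as a block the numbers were 97 in NK-like, 41 in dendritic-like and 194 in fibroblast-like cells, 12 for the T-like term and 142 for the NK-like term. Samples of the same number share nothing else in the labels, and their correlations after removing genotype were 0.280 in NK-like, 0.245 in macrophage-like, 0.280 in dendritic-like and 0.164 in fibroblast-like cells.

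Without 1 library the number of genes ran from 3 to 24 in NK-like, 0 to 1434 in macrophage-like, 0 to 866 in dendritic-like and 14 to 245 in fibroblast-like cells, from 3 to 292 for the T-like term and from 15 to 293 for the NK-like term. Changed lists ran from 3 to 10 in NK-like (10 in the main analysis) and from 5 to 9 in fibroblast-like cells (5). Changed shares ran from 0 to 2 (0 in the main analysis). With an estimated correlation 0 lists changed in NK-, macrophage-, dendritic-, fibroblast- and CD8 T-like cells (smallest adjusted p = 0.321, 0.469, 0.692, 0.316 and 0.983), and with fry 0 lists in each (0.0901, 0.337, 0.645, 0.269 and 0.569).

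Some results changed sign. Without 1 library the adjusted p ran from 3.0e-08 to 0.655 for the glycolysis list in NK-like cells, from 1.8e-06 to 0.516 for the oxidative phosphorylation list in NK-like cells (both up without WT 1) and from 8.1e-05 to 0.912 for the other cell: macrophage list in NK-like cells (down without 7KQ 2). The log2 change ran from -0.37 to 0.096 for Trp53 in NK-like cells, -0.65 to 0.38 for Cdkn1a in NK-like cells, -0.35 to 0.18 for Ccng1 in NK-like cells, -0.56 to 0.99 for Pdcd1 in NK-like cells, -0.32 to 1.97 for Ifng in NK-like cells, -0.0020 to 0.26 for Cd274 in NK-like cells and -1.07 to 0.34 for Mki67 in NK-like cells. Pdcd1 was 0.0075 with doublets kept and 0.020 with the replicate block (-0.03 in the main analysis). The p53 targets list in monocyte and macrophage-like cells had an adjusted p of 0.973 with marker gating and 0.693 to 0.981 without 1 library. Trp53 in monocyte and macrophage-like cells was 0.012 with gating and ran from -0.16 to 0.13, Zmat3 in monocyte and macrophage-like cells ran from -0.045 to 0.21, and Gzmg in monocyte and macrophage-like cells was -0.53 with gating, against 2.15. The adjusted p of the other cell: macrophage list in fibroblast-like cells ran from 4.7e-08 to 0.0838 (0.0030 and up without WT 2). The log2 change of Zmat3 in fibroblast-like cells ran from -0.91 to 0.35, of Cd274 in fibroblast-like cells from -0.13 to 1.80 and of Mki67 in fibroblast-like cells from -0.54 to 0.054. The share of macrophage-like cells was -0.087 with gating and ran from -0.062 to 0.30 without 1 library, that of unnamed cells was 0.18 with gating, that of fibroblast-like cells was -0.0013 with TMM over classes and ran from -0.11 to 0.47, and other T-like cells among T cells were 0.053 with doublets kept.

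Of the values under the alternatives, 82 for counts of genes, lists or shares stayed within 1.5 times the main count and 64 did not. Of the single genes, lists and shares, 33 changed sign, 788 kept their direction and side of the threshold, 48 kept the direction and lost the call, and 75 kept it and gained a call. Alternatives that gave no value for lack of cells were NK-like cells with scaling within library (41 in WT 1) and with gating (45), dendritic-like cells with gating (29 in 7KQ 1) and fibroblast-like cells with gating (0). At 2-fold the edgeR test recovered 22% of simulated changes in macrophage-like, 26% in NK-like and 20% in CD8 T-like cells at the observed spread, and 80%, 44% and 34% at a small simulated spread. CD8 T-like cells in WT 1 numbered 50 with scaling within library, 4 at resolution 2, 3 with gating, 2 with doublets kept and 1 with the stricter filter (2 in the main analysis).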

Other observations

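The values in this part were singled out after the data were seen, and no explanation was tested for them. The labels do not state whether the genotypes share 1 mouse substrain, so these values do not separate background from the p53 allele. In macrophage-like cells Tmeff1 stood at 3.29 and 4.14 CPM in WT 1 and WT 2 and 22.2 and 19.9 in 7KQ 1 and 7KQ 2. Msantd3, which lies beside Tmeff1 on chromosome 4 (48539935 to 48561919, and 48585174 to 48663131), stood in macrophage-like cells at 0.819 and 1.06 in WT and 4.35 and 4.83 in 7KQ, and Murc at 0.459 and 0.298 in WT and 2.39 and 2.19 in 7KQ. In dendritic-like cells Tmeff1 stood at 1.88 and 4.77 in WT and 3.31 and 4.46 in 7KQ. In fibroblast-like cells Msantd3 stood at 17.3 and 13 in WT and 17.7 and 13.4 in 7KQ.

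Nnt, a mitochondrial transhydrogenase whose reads are shared with a near-identical copy, stood at 17.9 and 17.1 CPM in WT and 7.12 and 7.38 in 7KQ macrophage-like cells. It stood at 9.87 and 12.7 in WT and 2.84 and 1.86 in 7KQ dendritic-like cells, and at 12.5 and 17.3 in WT and 3.93 and 3.69 in 7KQ NK-like cells. In fibroblast-like cells it stood at 14.1 and 10.3 in WT and 11.4 and 12.1 in 7KQ.

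An unnamed cluster with Ctsk among its leading genes held 169 cells of WT 1, 61 of WT 2, 4 of 7KQ 1 and 5 of 7KQ 2. The 2 clusters that carried both T cell and macrophage transcripts held 3, 42, 68 and 302 cells together in the same order.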
